A study of Drosophila melanogaster with 6 samples.

How the data were processed

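The series held 6 arrays, 3 of the tub-Gal4 driver strain and 3 of embryos with UAS-Sage under the same driver. Per the labels' protocols, embryos were aged at 25 C and sorted on a COPAS biosorter, RNA was extracted with TriZol and cleaned on a column, and the amplified RNA was labelled with a 3' in vitro transcription kit, which favours the 3' ends of transcripts. The deposited values were log2 signals per probe set. RMA and Partek are named in the submitters' processing notes, with no version. RMA subtracts background, equalises the distributions of the arrays and summarises the probes of a set, so values cannot show a change in total RNA per embryo and differences near the background are compressed. The test used by the authors is not given in the sources used here. Every value column was used.

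Of 18952 probe sets, 183 control probe sets were left out of the tests and 18769 were tested with no filter on dim signal. The platform annotation named exactly 1 gene for 13647 probe sets, several for 402 and none for 4720, and no gene was named from the latter kinds. Symbols of 13544 probe sets were updated through Entrez identifiers to the RefSeq annotation of Release 6, giving 11982 genes. No genome build is given for the array, so no coordinates were used. Where a gene had several probe sets, that with the highest mean over the 6 arrays stood for it.

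Groups were taken from the sample labels. The main test was limma 3.58.1 (lmFit and eBayes, in R 4.3.3) on the deposited log2 values, Sage minus control, two-sided, with no covariate and Benjamini-Hochberg adjustment at 0.05. Figures were drawn with matplotlib in Python. Gene lists (24 in number) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. Among the lists, fry, which asks whether a list's genes move one way on balance, gave adjusted p-values of 0.00847 for maternal transcripts, 0.00904 for salivary effector genes, 0.00847 for glue genes and 0.0348 for hemocyte genes, and above the threshold for the other lists, among them cuticle (0.122), secretory pathway (0.152), cell cycle (0.0691) and muscle (0.224). The lists overlap in some genes, the proneural list holds side, which is not a helix-loop-helix gene, the secretory list holds Sec5, of the exocyst, and several members, such as CrebA and all 6 Hsp70 genes listed, have no probe set naming them alone.

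The main test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The text names sage, fkh, sens, CrebA, PH4alphaSG1 and PH4alphaSG2, then the 12 largest rises and 12 largest falls among probe sets that name 1 gene, pass the threshold and do not overlap between groups, then up to 4 members per list (the 2 largest rises and 2 largest falls past the threshold, or the 2 largest differences where none passed). Papss, pip, PPO2, the heat shock genes other than stv and the genes of the closing section outside this rule were named after their values were seen.

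The procedure was tested on simulated data for the same comparison, with 18769 probe sets of which 200 were changed. It recovered 16.4% of those changed 1.5-fold, 58.2% of those changed 2-fold and 83.3% of those changed 4-fold, with 4 false calls among 109. A simulated shift of 0.5 in the secretory list was called and none of the 23 other lists were. Simulated probe sets varied independently, with the same spread in both groups, unlike those on the arrays. The correlation estimated in the data was 0.57 for the secretory list and 0.86 for the cell cycle list. The simulation therefore does not show how often camera at the preset correlation calls such lists falsely. Alternatives covered the replicate block, each array left out, 2 filters on dim probe sets, median centring, quantile normalization, a trended or robust prior, array weights, a test without moderation, 1 probe set per gene, other forms of camera and other probe sets of a gene. Alternatives added after the data were seen were an embryo-age score as a covariate, leaving out probe sets that varied among the controls, gene-by-gene array weights, a second list of maternal transcripts and families of genes sharing a symbol stem.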

Results

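RNA levels were measured on Affymetrix 3' expression arrays in whole Drosophila melanogaster embryos of stages 11 to 16. Sage is a basic helix-loop-helix transcription factor that is normally made in the embryonic salivary gland. In 3 samples it was expressed throughout the embryo from a UAS-Sage transgene under tub-Gal4, a driver active in most cells, and 3 samples of the tub-Gal4 strain served as controls. The labels describe the groups as matched in age and treatment. They do not say that the samples of a group came from separate collections, so p-values measure only the spread between these samples, which may be technical. The values were log2 signals, with array medians between 5.56 and 5.74, and the number of arrays (3 per group) limits the precision. Pearson's r across probe sets, which are not independent replicates, was 0.938 between control replicates 1 and 3, the least alike of a group, and 0.989 to 0.996 between Sage arrays. Control replicate 1 was closer to the Sage arrays (r of 0.962 to 0.972) than to control replicate 3. The median SD of a probe set was 0.160 in the controls and 0.114 with Sage. In the controls, 2343 probe sets differed by over 1 log2 unit between replicates, against 375 with Sage.

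The comparison asked which transcripts changed when Sage was present in the entire embryo. The sage transcript itself (CG12952) had a log2 signal of 7.52 ± 0.14 (SD, n = 3) in the controls and 12.47 ± 0.07 (SD, n = 3) with the transgene. The difference of 4.96 (SE 0.10), or 31.0-fold, had an adjusted p of 1.96e-05 by limma and was seen in 3 of 3 arrays. An exact two-sided permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. The signal came from 1 probe set, which does not separate the transgene from the endogenous gene.

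**Figure D1:**
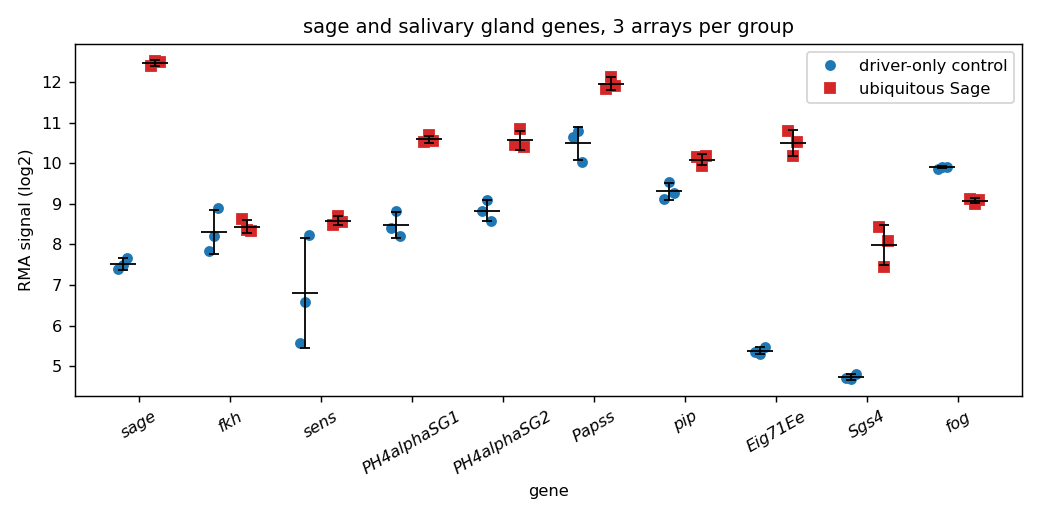
RMA signal (log2, vertical axis) of sage and 9 salivary gland genes (horizontal axis) in each of the 3 control arrays (circles) and 3 Sage arrays (squares), with the group mean and SD in black. Sage averaged 7.52 and 12.47 in the 2 groups, fkh 8.31 and 8.44, and the control arrays of sens were spread with an SD of 1.35.

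With Sage, 797 probe sets were higher and 1774 were lower at an adjusted p under 0.05 among 18769 tested, naming 694 and 1509 genes, 2 of them in both directions. Of these, 615 and 1584 changed at least 1.5-fold, and 117 and 204 at least 4-fold. The largest rises of named genes were those of CG14852, from 4.80 ± 0.23 to 11.08 ± 0.09 (77.8-fold), and CG14851, from 4.56 ± 0.11 to 10.57 ± 0.18 (64.6-fold; SD, n = 3 for each). CG11300 rose 62.5-fold, Jhbp14, of the juvenile hormone binding protein family, 56.2-fold, and CAH5, a carbonic anhydrase, 50.8-fold. CG10853 (40.2-fold), Eig71Ee (34.7-fold), Npc2e, of the sterol-binding Niemann-Pick type C2 family (32.0-fold), sage itself, CG9702 (26.2-fold), CG7443 (25.0-fold) and CG17134 (22.5-fold) completed the 12 largest rises. Their adjusted p-values lay between 1.96e-05 (CAH5) and 0.00241 (CG10853). Many of these genes were near the low end of the signal range in the controls, where RMA values compress differences.

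The 12 largest falls included genes with known roles in the ovary and egg. Marf1, a regulator of oocyte meiosis, went from 10.52 ± 0.73 to 5.58 ± 0.64 (30.7-fold; SD, n = 3), while its second probe set, at 4.99 in the controls, did not pass (log2 difference -0.15). CG4404 fell 28.3-fold, rpk, an ion channel gene, 26.4-fold, and swa, needed to localise bicoid RNA in the oocyte, 22.3-fold. plu, a maternal regulator of the embryonic S phase, fell 20.6-fold, and BigH1, the linker histone of the early embryo, 17.6-fold. wisp, a cytoplasmic poly(A) polymerase of the egg, fell 16.6-fold, tej and rhi, of the piRNA pathway, 15.6-fold and 15.4-fold, and tor, the terminal receptor tyrosine kinase, 15.05-fold. CG3679 fell 18.9-fold, and CG4911 had a log2 difference of -4.17. The adjusted p-values of these 12 lay between 0.000535 (CG4404) and 0.00443 (wisp). Several were near the low end of the signal range with Sage, among them CG4404 (4.71), tor (4.90) and rhi (5.08). The size and order of these falls are therefore approximate. The counts changed with each array left out. Such fits also have fewer residual degrees of freedom than the 4 of the reported test. Calls can therefore be lost, here and for the single genes below, without a change in the estimated difference. Higher probe sets numbered 1276 without control replicate 1, 465 without control replicate 2, and 446, 369 and 266 without Sage replicates 1, 2 and 3, and lower ones 1159, 1178 and 934 without Sage replicates 1, 2 and 3.

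**Figure D2:**
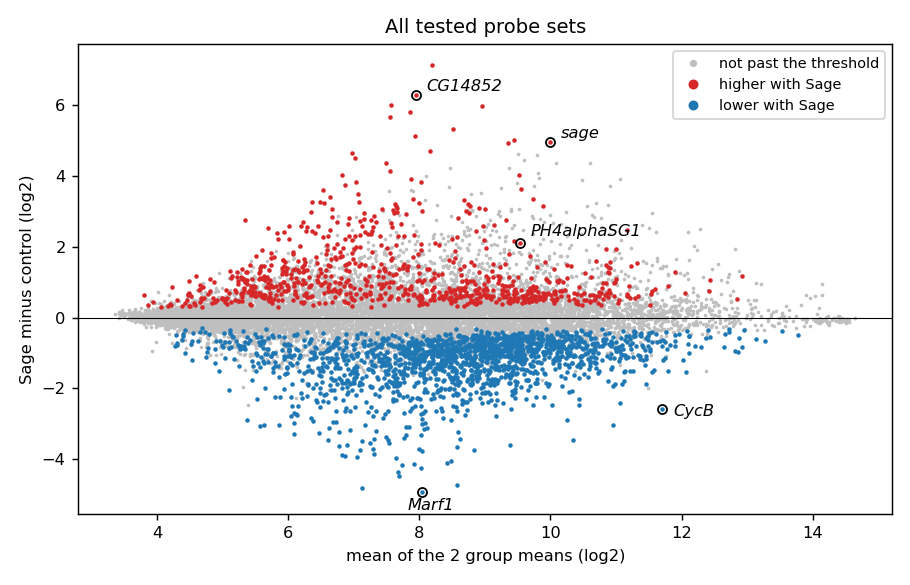
Log2 difference, Sage minus control (vertical axis), against the mean of the 2 group means (log2, horizontal axis) for the 18769 tested probe sets. Red points are the 797 higher and blue points the 1774 lower at an adjusted p under 0.05, and open circles mark 5 named genes, among them sage at 4.96 and Marf1 at -4.94.

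Genes with salivary gland expression or function that are not transcription factors included 6 that rose and 1 that fell among 25 measured. PH4alphaSG1 and PH4alphaSG2, salivary gland prolyl 4-hydroxylase subunits, rose from 8.48 ± 0.32 to 10.58 ± 0.09 (4.30-fold, adjusted p = 0.0015 by limma; SD, n = 3) and from 8.83 ± 0.26 to 10.56 ± 0.24 (3.33-fold, adjusted p = 0.0028 by limma; SD, n = 3). Eig71Ee and Sgs4, which encode products of the larval gland, rose 34.7-fold and 9.55-fold, and Papss and pip, of the sulfation pathway, also rose, by 1.47 and 0.77 on the log2 scale. The control signals of Eig71Ee (5.38) and Sgs4 (4.73) were near the low end of the range, so their folds are approximate. fog, which encodes a secreted signal for apical constriction, fell 1.77-fold. The list passed the camera test, upward (adjusted p = 0.0164), with a median difference of only 0.08 since 18 members did not pass. It did not hold with an estimated correlation (adjusted p = 0.727), without control replicate 1 (adjusted p = 0.092), with array weights (adjusted p = 0.113) or with ranks (adjusted p = 0.0712), and centring turned its median to -0.015. Adjusted over the list alone, 6 were higher and 1 lower.

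None of 11 measured regulators of the salivary gland passed, nor did any when adjusted over the list alone (camera adjusted p = 0.652). The forkhead factor gene fkh had a log2 difference of 0.12 (SE 0.27, adjusted p = 0.838 by limma), and passed with an embryo-age score as a covariate, added after the data were seen (0.75, adjusted p = 0.0267). The zinc finger gene sens had 1.78 (SE 0.65, adjusted p = 0.145 by limma), with control values spread by an SD of 1.35, and passed without control replicate 3 (log2 difference 2.50, adjusted p = 0.00413). pasilla (ps) had 0.41 (adjusted p = 0.567) and its other probe sets differed in sign, and it passed without Sage replicate 2 (adjusted p = 0.0447). No probe set named CrebA alone. With the age covariate the regulators passed as a list, as did the glue and prolyl 4-hydroxylase lists that follow. Of 12 glue and larval secretion genes, which share members with the list above, 3 rose and 9 did not pass (3 adjusted over the list alone; camera adjusted p = 0.096). Of 24 prolyl 4-hydroxylase alpha genes, PH4alphaSG1 and PH4alphaSG2 rose and 22 did not pass (2 adjusted over the list alone; camera adjusted p = 0.198).

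Components of the secretory pathway shifted upward as a list (camera adjusted p = 0.000453; median log2 difference 0.26), but did not pass with an estimated correlation (adjusted p = 0.727) or with array weights (adjusted p = 0.16). Of 34 measured, 6 rose and none fell, 11 rose when adjusted over the list alone, and 30 had a positive difference. TRAM, at the translocon, rose 1.63-fold and betaCOP, of the COPI coat, 1.55-fold. betaCOP did not pass without Sage replicate 1, 2 or 3 (adjusted p = 0.0915, 0.105 and 0.0977 by limma). Its log2 difference was then 0.64, 0.60 and 0.67, against 0.64 in the reported test. Of 22 endoplasmic reticulum chaperones and stress genes, none rose and 3 fell, among them PEK, a stress kinase (2.30-fold), and prtp (1.43-fold). PEK did not pass without Sage replicate 1, 2 or 3 (adjusted p = 0.0571, 0.0659 and 0.0605 by limma), nor prtp without Sage replicate 3 (adjusted p = 0.0605 by limma). Adjusted over the list alone, 5 rose and 5 fell. Its median (0.06) and mean (-0.01) differed in sign, and the list did not pass (camera adjusted p = 0.798).

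Germline and maternal transcripts were lower with Sage. Of 18 measured, 9 fell and none rose (10 fell adjusted over the list alone), with a median log2 difference of -1.07 (camera adjusted p = 6.33e-06; adjusted p = 0.727 with an estimated correlation). swa and plu fell most, by the folds given above. Of 18 cell cycle genes, 9 fell and none rose (9 adjusted over the list alone; median -0.94, camera adjusted p = 1.26e-05; adjusted p = 0.727 with an estimated correlation). CycB, a mitotic cyclin that also belongs to the maternal list, fell 5.96-fold, from 12.996 ± 0.15 to 10.42 ± 0.21 (SD, n = 3), and CycB3 fell 5.54-fold. Set against the mean of the Sage arrays, the cell cycle median was 0.57, 0.62 and 1.78 in control replicates 1, 2 and 3. Of 24 early patterning genes, bcd, a maternal RNA, fell 13.7-fold and 23 did not pass (1 adjusted over the list alone; median -0.26, camera adjusted p = 0.303), and a second, dim bcd probe set did not pass. That list passed without control replicate 1 (adjusted p = 0.00799) and changed sign without control replicate 3 (median 0.06).

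**Figure D3:**
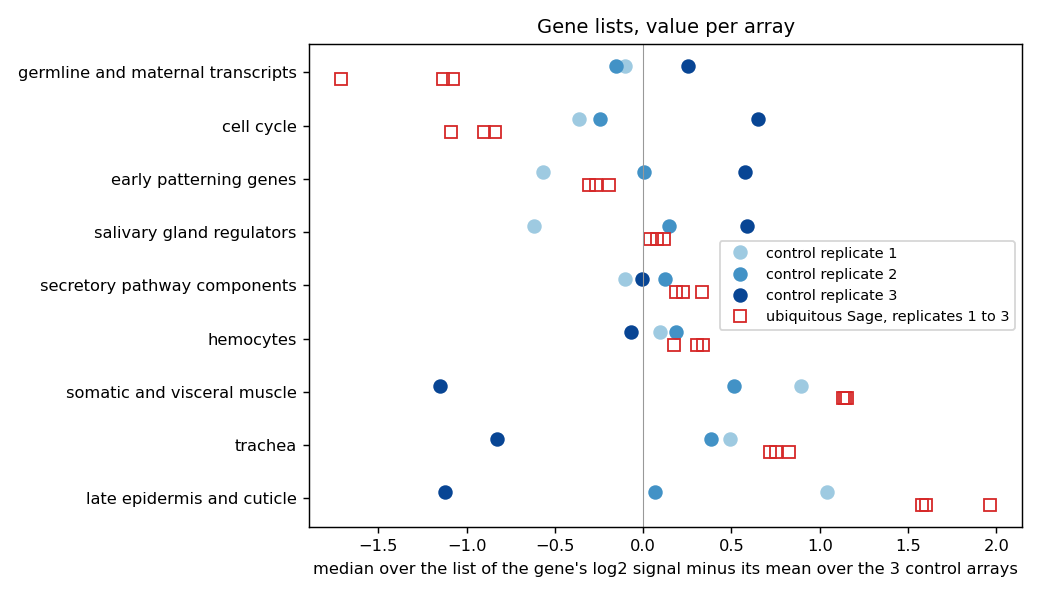
Median over each list (vertical axis) of the gene's log2 signal minus its mean over the 3 control arrays (horizontal axis), for each control array (filled circles, darker from replicate 1 to 3) and each Sage array (open squares). Cuticle genes lay at 1.04, 0.07 and -1.12 in the control arrays and between 1.58 and 1.96 with Sage, while maternal transcripts lay between -0.16 and 0.25 in the controls and between -1.71 and -1.08 with Sage.

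Genes of late epidermis and cuticle were higher with Sage, and the control arrays differed among themselves in the same genes. Of 41 measured, 6 rose and none fell (6 adjusted over the list alone; median log2 difference 1.82, camera adjusted p = 1.26e-05; adjusted p = 0.727 with an estimated correlation). TwdlN, a cuticle protein gene, rose 16.2-fold and Ccp84Ae 8.05-fold. TwdlN did not pass without control replicate 2 (adjusted p = 0.0618 by limma) or without Sage replicate 1, 2 or 3 (adjusted p = 0.0629, 0.0785 and 0.0886), nor Ccp84Ae without Sage replicate 2 or 3 (adjusted p = 0.0523 and 0.0579). Set against the mean of the Sage arrays, the list's median was -0.21 in control replicate 1, -1.51 in control replicate 2 and -3.05 in control replicate 3. Of 16 muscle genes, Obsc (3.10-fold) and Act79B (1.48-fold) rose, none when adjusted over the list alone (median 1.14, camera adjusted p = 0.0109; adjusted p = 0.727 with an estimated correlation), and a second, dim probe set of Obsc did not pass. Act79B did not pass without any one of the 6 arrays (adjusted p from 0.0583 without control replicate 2 to 0.151 without Sage replicate 3), nor Obsc without control replicate 2 (0.139) or without Sage replicate 1, 2 or 3 (0.147, 0.0935 and 0.18). The muscle medians against Sage were -0.15, -0.59 and -2.25 in control replicates 1, 2 and 3. Of 19 tracheal genes, uif rose 1.68-fold and 18 did not pass (none adjusted over the list alone; median 0.75, camera adjusted p = 0.0843), and a second, dim uif probe set gave -0.0025. uif did not pass without control replicate 1 (adjusted p = 0.0713) or without Sage replicate 1, 2 or 3 (0.12, 0.128 and 0.135). None of 16 neuronal genes passed (none adjusted over the list alone; camera adjusted p = 0.385), and Gad1 and Syn had log2 differences of 1.75 and 1.60 with control SDs of 1.93 and 1.82.

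Of 19 hemocyte genes, PPO1, PPO2 and Pxn rose and 16 did not pass (3 adjusted over the list alone; camera adjusted p = 0.0843, fry adjusted p = 0.0348), with PPO1, a prophenoloxidase of crystal cells, 3.04-fold higher and Pxn, peroxidasin, 2.69-fold higher, though a second, dim Pxn probe set gave -0.01. PPO1 did not pass without control replicate 2 (adjusted p = 0.0568) or without Sage replicate 1, 2 or 3 (0.0941, 0.101 and 0.108). Of 10 glial genes, wrapper rose 1.75-fold and Indy fell 1.74-fold (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.198), and Indy did not pass without control replicate 2 (0.0645) or without Sage replicate 1, 2 or 3 (0.104, 0.0832 and 0.101). Of 11 genes of fat body and yolk, the yolk protein gene Yp3 rose 2.27-fold (1 adjusted over the list alone; camera adjusted p = 0.626). None of 19 gut genes passed (none adjusted over the list alone; camera adjusted p = 0.514), with Vha100-4 and LManV at log2 differences of 1.33 and 0.98, LManV passing without control replicate 1 (adjusted p = 0.0323). Of 34 helix-loop-helix and proneural genes, net rose 2.47-fold (1 adjusted over the list alone; camera adjusted p = 0.896), and the list's median (-0.08) and mean (-0.08) were opposite in sign to its test.

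Of 12 apoptosis and DNA damage genes, 3 fell, among them the caspase gene Dronc (2.68-fold) and p53 (2.26-fold), whose second, dim probe set did not pass (1 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.303). Of 5 heat shock genes with a probe set of their own, stv, a co-chaperone gene, rose 1.91-fold, and the other 4 had negative differences that did not pass, Hsp26 at -1.99, Hsp68 at -1.59, Hsp27 at -1.35 and DnaJ-1 at -0.61 (1 rose adjusted over the list alone; median -1.35, camera adjusted p = 0.626). stv did not pass without control replicate 1 or 3 (adjusted p = 0.0669 and 0.0514) or without Sage replicate 1, 2 or 3 (0.0708, 0.13 and 0.14). Of 11 immune genes, PGRP-LB rose 1.72-fold (1 adjusted over the list alone; camera adjusted p = 0.31), but did not pass without Sage replicate 2 or 3 (0.0522 and 0.064). Of 24 ecdysone response genes, Hr4 fell 1.61-fold (none adjusted over the list alone; camera adjusted p = 0.626) and its other probe sets, both dim, did not pass. Hr4 did not pass without control replicate 2 (adjusted p = 0.0671) or without Sage replicate 1, 2 or 3 (0.143, 0.103 and 0.182). Neither tra (log2 difference -0.65) nor Sxl (0.30) nor the other 2 sex-dependent transcripts passed (none adjusted over the list alone; camera adjusted p = 0.679), and that list's median (0.09) and mean (-0.04) differed in sign. The colour genes y and ry, which transgenes can carry, had differences of 0.84 and 0.77 and did not pass (adjusted p = 0.241 and 0.0501 by limma; 1 rose adjusted over the list alone; camera adjusted p = 0.198). Without control replicate 1 both passed (adjusted p = 0.0135 and 0.0158), and ry also without control replicate 3 (0.0404). The median of y and ry against Sage was -0.20, -1.07 and -1.13 in control replicates 1, 2 and 3. y also belongs to the cuticle list, and no probe set named w, another colour gene of this list, alone.

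Signals of the control RNAs for labelling and hybridisation differed between the groups, the labelling ones at levels near or below the array medians. The hybridisation control BioB was 1.39 log2 units higher on the Sage arrays and the labelling control Dap was lower, with a difference of -0.66, with no overlap between the groups (exact permutation p = 0.1, the smallest possible, n = 3). The signal of 3' over 5' probe sets was also higher with Sage for Act5C (by 0.61), eIF4A (0.43) and GAPDH (0.51), each without overlap. The groups separate completely in these measures, so handling batch and group cannot be told apart for any gene group above.

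**Figure D4:**
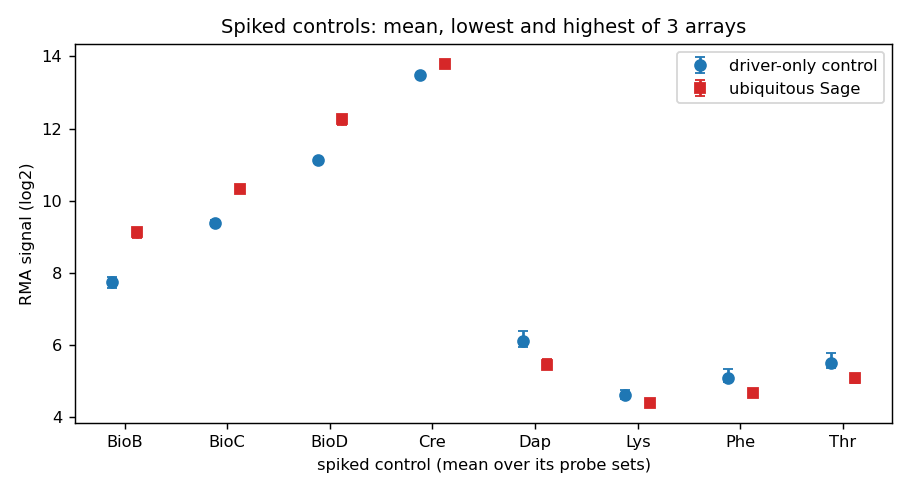
RMA signal (log2, vertical axis) of 8 spiked control RNAs (horizontal axis), as the group mean with the lowest and highest of 3 arrays, for control (circles) and Sage arrays (squares). BioB averaged 7.73 in the controls and 9.12 with Sage, and Dap 6.09 and 5.43.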

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

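All tests in this part were chosen after the result was seen. Control RNAs of bacterial and phage origin, which do not come from the embryo and enter no gene comparison, differed between the groups. The hybridisation controls, added in fixed amounts, were higher on the Sage arrays by 1.39 (BioB), 0.95 (BioC), 1.14 (BioD) and 0.33 (Cre) log2 units. The labelling controls were lower there, with differences of -0.66 (Dap), -0.21 (Lys), -0.43 (Phe) and -0.44 (Thr). Their group means lay between 4.39 (Lys with Sage) and 6.09 (Dap in the controls), near or below the array medians, which limits these 4 differences. In each of these 8 families the lowest array of one group lay above the highest of the other, and the exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 can give. Chance gives such a separation in 10% of comparisons, and it was seen in 34.7% of the 18769 tested probe sets.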

How the results depend on the processing

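Tests with the embryo-age covariate, without probe sets varying among the controls and with gene-by-gene array weights were chosen after the data were seen. The sage difference stayed past the threshold in every alternative run (4.86 to 5.12), and no probe set called in the reported test was called in the opposite direction under any. Replicate numbers did not pair the arrays (correlations of deviations -0.13, -0.07 and -0.25). With the replicate block, 341 probe sets were higher, 341 at least 1.5-fold, and 1057 lower, with 330 and 1056 of them shared with the reported calls. The test without moderation gave 353 higher and 1026 lower (252 and 930 at least 1.5-fold).

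Array weights gave 4869 higher and 4922 lower, with 1582 at least 1.5-fold higher, and their estimation stopped before it converged. Gene-by-gene weights, added after those calls had been seen, gave 2243, 2771 and 1236. Among lists, the choice decides 2 calls: with the default weights the salivary effector list (adjusted p = 0.113, median 0.10) and the secretory list (adjusted p = 0.16, median 0.11) no longer passed, and with gene-by-gene weights both did (adjusted p = 0.0358 and 0.0402). Among named genes, LManV (adjusted p = 0.00333), tra (0.00367), Gad1 (0.00712), Syn (0.0216) and ps (0.0374) passed with the default weights and not with gene-by-gene ones. Neither version is preferred here. Centring gave 24.4% of calls higher and quantile normalization 35.4%, against 31.0%. Leaving out each array in turn gave 266 (Sage replicate 3) to 1276 (control replicate 1) higher and 934 (Sage replicate 3) to 2035 (control replicate 1) lower, with 259 to 1150 higher and 927 to 1857 lower at least 1.5-fold. Each of these fits left out a single array, and counts lay on both sides of the reported 797 and 1774. The cause was not tested.

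With an estimated correlation none of the 6 lists passed (adjusted p = 0.727), at unchanged medians of 1.14 (muscle), 1.82 (cuticle), 0.077 (salivary effectors), -1.07 (maternal), 0.26 (secretory) and -0.94 (cell cycle). The shared 0.727 comes from the adjustment. Unadjusted camera p-values were 0.0886 (maternal), 0.117 (salivary effectors), 0.2 (cuticle), 0.256 (cell cycle), 0.325 (muscle) and 0.364 (secretory). The correlation was estimated with only 4 residual degrees of freedom, and the power of that form was not tested. With ranks the salivary effectors (0.077) did not pass. Centring brought hemocytes (0.18) and trachea (0.66) past the threshold and turned the salivary effector median to -0.015. The filter at the median brought in the prolyl 4-hydroxylases (1.15) and glue genes (4.19), with fewer genes tested. It used the mean over all 6 arrays, so genes that are low in the controls can stay through their Sage values. These gained calls therefore add no support. Without probe sets varying among controls, cuticle (0.21) and muscle (0.24) did not pass. With the age covariate, made from cuticle, muscle and tracheal genes, cuticle (0.12) did not pass, muscle (-0.45), trachea (-0.22), neurons (-0.48), gut (-0.033), early patterning (0.43) and heat shock (0.46) reversed, and salivary regulators (0.56), proneural genes (0.33), glue genes (0.096) and prolyl 4-hydroxylases (0.13) passed. Over single arrays left out, medians ranged from -0.12 to 0.29 (salivary regulators), 0.062 to 0.16 (salivary effectors), 0.048 to 0.11 (chaperones), -0.24 to 0.13 (proneural), 0.21 to 0.32 (hemocytes), 0.22 to 0.93 (trachea), -0.55 to 0.056 (early patterning) and -0.039 to 0.17 (sex-dependent).

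Other list reversals concerned results past the threshold in neither fit. The tested direction turned for proneural genes with array weights (-0.15), gene-by-gene weights (-0.027) and ranks (-0.081), chaperones with array weights (-0.0035) and gene-by-gene weights (0.0093), fat body with array weights (-0.048), ecdysone genes with the median filter (0.047) and sex-dependent transcripts with the mean over probe sets (0.029). Among named genes, fkh ranged from -0.11 to 0.42 over single arrays left out and passed with the age covariate (0.75, adjusted p = 0.0267), and with that covariate tra (0.085), LManV (-0.56), Syn (-0.47) and Gad1 (-0.49) reversed. Other probe sets, none past the threshold, reversed for uif (-0.0025), Pxn (-0.0067) and Hr4 (0.085), whose reported values passed, and for Sxl (-0.090) and ps (-0.45 and -0.58). For these the cause was not tested. Named genes kept direction and side of the threshold in 1041 further tests, lost the threshold in 90 and gained it in 30. The list test has no separate value without moderation or with 1 probe set per gene. Signal near background limits dim probe sets.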

Other observations

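Families of genes that share a symbol stem were tested with camera after the data had been seen, 115 in all. The Cpr cuticle protein genes were higher with Sage, with 12 of 66 past the threshold and a median log2 difference of 0.63 (adjusted p = 1.05e-07), as were Lcp genes, 2 of 7 (0.88, adjusted p = 0.0169). The Cpr family shares members with the cuticle list, in which the control arrays differed. That list's medians against Sage were -0.21, -1.51 and -3.05 in control replicates 1, 2 and 3. Nup genes of the nuclear pore were lower, 12 of 20 (-0.90, adjusted p = 0.000103), as were CSN genes of the COP9 signalosome, 6 of 8 (-0.88, adjusted p = 0.000291), dgt genes of the augmin complex, 4 of 6 (-1.35, adjusted p = 0.0243), and Prosbeta genes of the proteasome, 5 of 12 (-0.50, adjusted p = 0.0278). These directions held with centred and with quantile-normalized values. None of the families passed with an estimated correlation (adjusted p = 0.906). The adjustment gave that same value to every family named here, so it does not rank them. The mRpL genes of the mitochondrial ribosome shifted upward (median 0.22, adjusted p = 0.0296) with 1 of 44 higher and 1 lower. Of 47 Obp genes 7 rose (adjusted p = 0.0315), but the family did not pass after quantile normalization (adjusted p = 0.0762) and its median was -0.02 after centring. Prp and Taf genes were lower, 4 of 11 and 4 of 13 (camera adjusted p = 0.0181 and 0.0291). The Taf family did not pass after quantile normalization (camera adjusted p = 0.0585).

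Among the tests below, that on the second maternal list and the count of splits were set before their results were seen, and the others after. Most of those others replaced first forms whose values had already been seen. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many calls as the real one, itself, with 2571 probe sets, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached.

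Maternal transcripts were lower with Sage. Embryos of the segmentation stages among the controls stay open as a source. Of 22 zygotic patterning genes, 0, or 0%, were higher in each control array than in the mean Sage array, against 14 of 18 maternal genes, but control replicate 1 alone decides this. The patterning medians against Sage were -0.33, 0.22 and 0.80 in control replicates 1, 2 and 3, and without control replicate 1, 12 of the 22 were higher in both others. Eggs or embryos from before zygotic patterning in the control collections may also be a source. A second list of 24 maternal genes had a median difference of -0.80, past the bound set beforehand, but 11 of them fell, short of the 50% also required, so the test did not decide. Falls in that list would also follow from the other sources named here, so even a pass could not have told these sources apart. Among them mael (-2.45), krimp (-2.51) and zuc (-2.56) fell, while orb (-0.05) and alphaTub67C (0.19) did not pass. Separate handling also stays open, since all 8 spiked control families separated the groups, as does an effect of Sage on clearance of maternal RNA, which was not tested. Differences between the strains other than the transgene were not tested either.

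Cuticle and muscle genes were higher with Sage as lists by camera at the preset correlation, but not with an estimated one (adjusted p = 0.727). Tracheal genes did not pass (camera adjusted p = 0.0843). Older embryos in the Sage collections stay open as a source. Muscle and tracheal genes outside the cuticle list, 34 in all, had a median difference of 0.97, with medians of -0.12, -0.49 and -2.06 against Sage in control replicates 1, 2 and 3, but their lists were already known to differ, so they do not decide. Neither neuronal nor gut genes passed as a list (adjusted p = 0.385 and 0.514). The mean signal over 75 genes of cuticle, muscle and trachea was 9.45, 8.71 and 7.22 in the control arrays and 9.67 to 9.91 with Sage. Dilution by maternal RNA, as the whole source, would raise zygotic genes by one factor. Against it, the median difference was 1.82 for cuticle genes and 0.12 for salivary regulators (SD over the 11 genes 0.57). That gap came from control replicates 2 and 3. Against Sage, medians in control replicates 1, 2 and 3 were -0.21, -1.51 and -3.05 for cuticle genes and -0.56, -0.05 and 0.33 for regulators. In control replicate 1 the regulators lay lower than the cuticle genes, so that array does not speak against dilution. Dilution beside a difference in age stays open. Against control replicate 1 cuticle genes ranged from -0.63 to 2.26, though 65.9% of the 41 lay within 0.5 of their median. An effect of Sage on these genes cannot be separated from age, handling or other differences between the strains in this design.

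Salivary gland effector genes, 25 in all, passed as a list at the preset correlation with a median difference of 0.077; 6 of them rose and 1 fell. Older embryos stay open as a source of these 6 rises. The values below argue only against rises in step with the age score, which was made from cuticle, muscle and tracheal genes. That score did not overlap between the groups (at most 9.45 in the controls, at least 9.67 with Sage), so the adjusted values reach beyond the controls. With the age score as a covariate the muscle median turned to -0.45 and 433 of 797 higher probe sets stayed past the threshold, while all 6 stayed, with a median of 1.75 (1.92 before; lowest 0.81, SE 0.19), as did the list (median 0.16, adjusted p = 0.00337 at the preset correlation; not past the threshold with an estimated one, with or without the score, adjusted p = 0.673 and 0.727). Dilution by maternal RNA stays open too. As the whole source it would raise salivary regulators about as much, and their median was 0.12 (SD over the 11 genes 0.57). That lay below the 6 rises, but the 6 were picked because they passed, which favours large rises. Over all 25 effector genes the median was 0.077, no higher than that of the regulators. However, Sgs1, Sgs3, Sgs5, Sgs7, Sgs8 and ng1 to ng4 had means from 3.85 (ng1) to 5.63 (Sgs5) in both groups. Genes so near the low end of the signal range cannot show a factor, so the comparison of medians does not decide. The 25 differences ran from -0.82 (fog) to 5.12 (Eig71Ee), with an SD of 1.28. A single factor for all 25 would not give that spread, though genes near the low end add to it. Whole-list forms of the age and dilution tests left both open and were replaced after their values had been seen. Separate handling was not tested apart from the groups, since all 8 spiked control families separated them. An effect of Sage, which the design names, may account for the rises but was not told apart from handling. The controls were of the driver strain, so other differences between the strains were not told apart from Sage either. With the age covariate sens had a difference of 3.35 (adjusted p = 0.000298; 0.00018 to 0.327 over its alternatives), an observation made after the control spread was seen.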
